A study of Oryza sativa Japonica Group with 12 samples.

How the data were processed

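Shoots of 30-day rice seedlings of a wild-type line and of the daikoku1 mutant were treated with 120 mM KCl or 120 mM KNO3 for 90 min, and total RNA labelled with Cy3 was hybridised to custom 1-colour Agilent arrays, 1 sample per array. Per the file headers, the deposited scanner files hold intensity values per spot that Agilent Feature Extraction 11.5.1.1 corrected for background and spatial trend within each array and did not normalise between arrays. The deposited value table holds log2 values that the authors shifted so that the 75th percentile of each array is 0, after setting signals below 1 to 1. Each of its columns was checked against the scanner file of the same array and correlated with it at 0.9999 or more. The 75th percentile of the signals lay between 203 and 405, 59.9% to 69.3% of probes were well above background per array, and 0 spots were saturated. For arrays, their number limits the precision.

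Of 62976 spots per array, 61657 were not controls. They belonged to 60045 probes, of which 59 design controls were left out and 59986 kept. Spots of 1 probe were averaged, and spots that the scanner software marked as uneven or as outliers within their probe were left out. The probes stood for 42896 genes or other targets, 42487 of them rice loci, and 17353 carried an informative name. For 6036 probes the locus was taken from the probe name, and for 1358 probes the locus in the annotation differed from that in the probe name. Of 4064 probes with a RefSeq transcript accession, 0 matched the gene table supplied, so no gene was named from that table. The array names a genome build and gives no coordinates.

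Signals were taken as log2 of the processed signal minus the 75th percentile of the array. A probe was kept when it was well above background on at least 2 arrays of a group, which left 42664 probes. Where several probes measured 1 gene, the probe with the highest mean signal was tested, which gave 28607 genes. They held 643 missing values, and 28113 genes had none. A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (8 residual and 2.75 prior degrees of freedom) and p-values adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. All tests were two-sided. The comparisons were KNO3 against KCl in wild type and in mutant, mutant against wild type in KCl and in KNO3, the interaction of salt and genotype, and the averages of the nitrate and of the genotype effect. Pairs of effects that share no array were compared by Pearson and Spearman correlation across genes.

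The 30 gene lists, among them markers of cell types, were written before the data were examined, as search terms on gene names and as loci. After the annotation and preliminary gene counts had been seen, the search terms of 15 lists were edited from the names alone, because they matched inside other words. The edits left out 152 members and added 0. The lists as first written were kept as an alternative. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation.

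Genes were named by a rule written before the data were examined. In each comparison the rule takes RGA1, the 10 highest and 10 lowest changes among genes past the threshold with an informative name whose replicates did not overlap, each gene of the nitrate and nitrite reduction list, and up to 4 members of each other list with the smallest p. Genes outside the rule are named as chosen after their values were seen.

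The alternatives chosen before the data were examined were normexp background correction with an offset of 50, quantile normalization, no filter on dim probes, a filter on all 12 arrays, a test per probe, slide as a block, each slide alone, replicate number as a block, the value table in place of the scanner files, an estimated correlation in camera, and leaving out each array in turn. Scan as a block, scan 1 alone, scan 4 alone, leaving out the 3 arrays of the low-gain scan, and the lists as first written were added after the data were seen. Other splits of the arrays were counted, 10 for each comparison of 3 against 3 and 100 drawn with a fixed seed for the others. The order of loci was compared with 1000 random gene sets, in windows of 20 tested loci.

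The fit was tested on simulated data with 200 changed genes among 28113. The noise was normal and independent between genes and arrays, with the residual spreads of the real fit shuffled over genes. It held no slide or scan effect and no difference in noise between arrays, so the rates hold for such noise only. At a 4-fold change it recovered 44% of the changed genes in wild type, 41% in mutant, 47% in KCl, 30% in KNO3, 0% for the interaction, 73% for the average nitrate effect and 75% for the average genotype effect. At a 2-fold change it recovered 2% in wild type, 3% in mutant, 4% in KCl, 2% in KNO3, 0% for the interaction, 23% for the average nitrate effect and 18% for the average genotype effect. The fits made 0 to 6 false calls in these simulations. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.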

Results

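Gene expression was measured in shoots of rice seedlings, in a wild-type line and in the daikoku1 mutant of the G protein alpha subunit gene RGA1. Per the labels, the seedlings grew for 30 days and then for a short time without nitrogen. Their excised shoots were floated in 120 mM KCl, the control, or in 120 mM KNO3 for 90 min. What is called the nitrate effect is the difference between these salts, which differ in both nitrate and chloride. The 12 samples formed 4 groups of 3, wild type in KCl, wild type in KNO3, mutant in KCl and mutant in KNO3, and each was hybridised to its own 1-colour array. The 75th percentile of the processed signal lay between 203 and 405 intensity units, 59.9% to 69.3% of the probes of an array were well above background, and the number of arrays limits the precision. Values are log2 signals relative to the 75th percentile of the array. A change is a difference of 2 group means on that scale with its standard error, n = 3 arrays per group, and an adjusted p from limma. The labels do not say whether the samples of a group came from separate plants, so these p-values measure the spread between these samples. Where a gene was not well above background on any array of 1 group, the fold is a lower bound, set by the lowest signal well above background on those arrays or by the gene's own signal where that was higher, and is written "at least". A gene counted as well above background on an array, or as measured there, when any of its probes that passed the filter was. The tested probe itself may have been dimmer. The array names a genome build, IRGSP5:v5:Jun2008, without coordinates, so genes carry their locus identifiers and the names printed in the array files.

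RGA1 (Os05g0333200), the gene of the mutation, fell in the mutant in both salts. Its signal was 0.43 ± 0.11 (SD, n = 3) in wild type in KCl, 0.42 ± 0.09 in wild type in KNO3, -5.40 ± 0.54 in mutant in KCl and -4.72 ± 0.58 in mutant in KNO3, a genotype difference of -5.83 ± 0.34, adjusted p = 2.93e-06 in KCl and -5.15 ± 0.34, adjusted p = 9.36e-06 in KNO3. All 7 probes of RGA1 were well above background on each wild-type array, and 0 to 4 of the 7 were on each mutant array. In mutant in KCl the tested probe lay close to the lowest signal well above background, so the size of that difference rests on signals near background. The 7 probes were lower in the mutant with a median of -6.26 in KCl and -5.90 in KNO3, and all 7 passed in each salt. RGA1 did not pass for nitrate in wild type (-0.01 ± 0.34, adjusted p = 0.99) or in mutant (0.68 ± 0.34, adjusted p = 0.225), where 1 of its 7 probes passed. Where the probes lie relative to the lesion is not stated in the files.

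**Figure D1:**
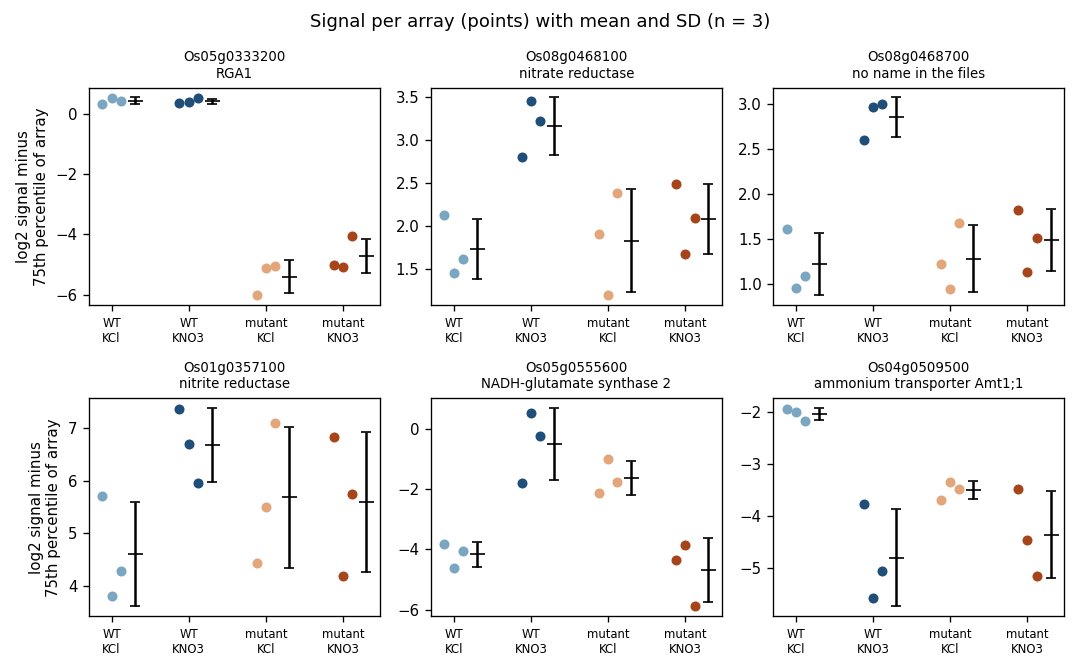
Signal of 6 loci on each of the 12 arrays (log2, relative to the 75th percentile of the array) with group means and SD (n = 3), where WT stands for wild type. RGA1 lay between 0.31 and 0.54 on the wild-type arrays and between -6.03 and -4.06 on the mutant arrays.

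Across the 28607 genes tested, the arrays separated by salt along the first principal component, which held 43.2% of the variance over the 28113 genes without missing values. The KCl arrays scored between -110 and -54.5 on it, wild-type KNO3 arrays 53.1, 169 and 176, and mutant KNO3 arrays 22.3, 24.9 and 102. Each array correlated with the others of its group at a mean of 0.911 to 0.966, the lowest being wild-type KNO3 replicate 1. The arrays lay on 2 slides and came from 4 scans. Slide 1 held 8 arrays of all 4 groups, 1 of them mutant KNO3, and slide 2 held wild-type KCl replicate 3, wild-type KNO3 replicate 3 and mutant KNO3 replicates 2 and 3. Scan 1 held 7 arrays of slide 1 and scan 4 held the 3 nitrate arrays of slide 2. Scans 2 and 3 held 1 array each. Scan 4 had a lower photomultiplier gain (377 against 430 to 469) and 9.77% to 18.5% of its signals lay below 1, against at most 0.889% on the other arrays.

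**Figure D2:**
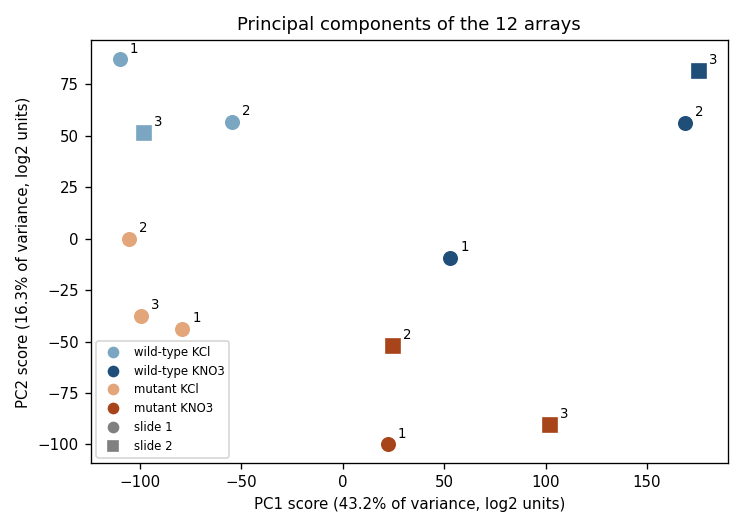
Scores of the 12 arrays on the first and second principal components (43.2% and 16.3% of the variance), coloured by group, shaped by slide and numbered by replicate. The KNO3 arrays score 22.3 or more and the KCl arrays at -54.5 or below on the first component.

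The first comparison asked which genes respond to nitrate in wild-type shoots. In KNO3 a homologue of 4,5-DOPA dioxygenase (Os01g0878900) rose by 9.86 ± 1.21, adjusted p = 0.00223, the EF-hand protein Os09g0483500 by 9.47 ± 0.68, adjusted p = 0.000196, and a phosphoenolpyruvate carboxykinase (Os10g0204400, 2 of 3 KCl arrays) by 8.25 ± 1.01, adjusted p = 0.00223. A class III chitinase (Os11g0701000) rose by 8.06 ± 1.16, adjusted p = 0.0034, although only 1 of 3 KCl arrays measured it. The glutathione S-transferase GST6 (Os09g0367700) fell by 7.90 ± 1.57 (adjusted p = 0.00882). The tau class GST protein 4 (Os10g0528300, -6.56 ± 1.45) and the peroxidase BP 1 (Os01g0963000, -5.75 ± 0.32) fell too. Genes near background in KCl were the EF-hand protein Os09g0483100, at least 171-fold higher in KNO3 (adjusted p = 0.00162), and a glutathione S-transferase TSI-1 (Os10g0530000), at least 296-fold higher. Isocitrate lyase (Os07g0529000) was not well above background on the KNO3 arrays and at least 78.9-fold lower there (adjusted p = 0.00714). The cytochrome P450 Os08g0508000 was at least 25.2-fold lower and the FPF1-like protein RAA1 (Os04g0282400) at least 36.5-fold lower.

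Among the genes of nitrate and nitrite reduction in wild type, a nitrate reductase (Os08g0468100) rose by 1.44 ± 0.36, adjusted p = 0.0193. The locus Os08g0468700, which the list named in advance and the array leaves without a name, rose by 1.63 ± 0.29, adjusted p = 0.00641. Ferredoxin-nitrite reductase (Os01g0357100) did not pass (2.08 ± 0.81, adjusted p = 0.0895), nor did the nitrate reductase Os02g0770800 (1.23 ± 1.16, adjusted p = 0.477). The molybdenum cofactor protein CNX2 (Os12g0507000) fell by 1.65 ± 0.42 (adjusted p = 0.022). In this list, of 7 genes, 2 rose and 1 fell (adjusted over the list alone, 4 and 1). Its shift did not pass (adjusted p = 0.155). In ammonium assimilation the NADH-glutamate synthase 2 Os05g0555600 rose by 3.67 ± 0.64, adjusted p = 0.00576, 1 of 14 genes to pass. In the supply of reductant and carbon, glucose-6-phosphate dehydrogenase (Os03g0412800, 2.12 ± 0.41) and the root isozyme of ferredoxin-NADP reductase (Os03g0784700, 1.59 ± 0.50) rose. The phosphoenolpyruvate carboxylases Os08g0366000 (-2.44 ± 0.43) and Os02g0244700 (-1.51 ± 0.36) fell.

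Nitrate transporters rose in wild type, Os03g0103000 by 3.65 ± 0.80, with 1 of 3 KCl arrays measuring it, and Os10g0554200 by 2.63 ± 0.68. The low affinity transporter Os03g0235900 rose by 1.38 ± 0.42 and Os03g0193300 by 0.94 ± 0.27. Ammonium transporter Amt1;1 (Os04g0509500) fell by 2.77 ± 0.48, with 2 of 3 KNO3 arrays measuring it. Ammonium transporter Os02g0620600 fell by 2.44 ± 0.47, with 1 of 3 KNO3 arrays measuring it, and Os11g0105300 was at least 3.57-fold lower. The ammonium transporter list shifted down as a whole (median -1.20, adjusted p = 0.0185, adjusted p = 0.551 with an estimated correlation). Of 10 genes, 0 rose and 3 fell (adjusted over the list alone, 0 and 3), and the median was -1.20 with slide as a block and -0.77 within slide 1. Among nitrate transporters, of 11 genes, 4 rose and 0 fell (adjusted over the list alone, 5 and 0), and the shift of the list did not pass (adjusted p = 0.112). The non-symbiotic haemoglobins 3 (Os03g0234000, 2.51 ± 0.64) and 4 (Os03g0234100, at least 5.29-fold, 2 of 3 KNO3 arrays) rose and a NIN-like protein 2 (Os04g0495800, -1.17 ± 0.20) fell.

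In hormone pathways of wild type, the A-type response regulators 1 (Os04g0442300, at least 12.2-fold, with 1 of its 3 probes passing) and 2 (Os02g0557800, 1.80 ± 0.31) and cytokinin dehydrogenase 5 (Os01g0775400, 3.89 ± 0.71) rose. Gibberellin 20-oxidase 1 (Os03g0856700) rose by 1.75 ± 0.56 and gibberellin 20-oxidase 2 (Os01g0883800) fell by 1.94 ± 0.41. The auxin list shifted up (median 0.25, adjusted p = 0.0275, adjusted p = 0.131 with an estimated correlation). Of 106 genes, 22 rose and 9 fell (adjusted over the list alone, 22 and 9), and the median was 0.25 with slide as a block and 0.20 within slide 1. The auxin-responsive IAA23 (Os06g0597000) rose by 2.61 ± 0.32 and a YUCCA-like gene 4 (Os01g0224700) was at least 3.55-fold lower. Sucrose synthase 1 (Os03g0401300, 4.74 ± 0.84) and sucrose synthase 2 (Os06g0194900, 1.82 ± 0.33) rose, and the potassium transporter HAK1 (Os03g0574900) was at least 6.62-fold lower.

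Photosynthetic light reactions shifted up in wild type (median 0.50, adjusted p = 0.0241, adjusted p = 0.832 with an estimated correlation). Of 71 genes, 11 rose and 2 fell (adjusted over the list alone, 10 and 1), and the median was 0.50 with slide as a block and 1.07 within slide 1. Chlorophyll a/b-binding protein 2 (Os01g0600900) rose by 3.99 ± 0.70. The Calvin cycle and photorespiration shifted up (median 0.44, adjusted p = 0.0256, adjusted p = 0.595 with an estimated correlation, and adjusted p = 0.055 with the list as first written). Of 19 genes, 2 rose and 0 fell (adjusted over the list alone, 2 and 0), and the median was 0.44 with slide as a block and 0.61 within slide 1. Expansins and cellulose synthases shifted up (median 0.45, adjusted p = 0.0129, adjusted p = 0.595 with an estimated correlation). Of 50 genes, 14 rose and 2 fell (adjusted over the list alone, 14 and 4), and the median was 0.45 with slide as a block and 0.38 within slide 1. A cellulose synthase (Os07g0552800) rose by 3.17 ± 0.52. Cytosolic ribosomal proteins shifted down (median -0.61, adjusted p = 5.06e-06, adjusted p = 0.691 with an estimated correlation). Of 140 genes, 0 rose and 17 fell (adjusted over the list alone, 0 and 9), and the median was -0.61 with slide as a block and -0.44 within slide 1. The 40S proteins S20 (Os06g0134000, -1.47 ± 0.32) and S8 (Os02g0489400, -1.62 ± 0.37) were among those that fell. Each of these list calls used a preset correlation between genes, and none of the 27 over the 7 comparisons held with an estimated correlation.

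In all, 6235 of 28607 genes passed in wild type, 2924 higher and 3311 lower in KNO3, a balance that turned within slide 1 (194 and 155), without wild-type KCl replicate 1 (1271 and 1218) and without wild-type KNO3 replicate 2 (1068 and 1009). Replicates did not overlap for 6082 of them, and for 40.9% of all genes, where chance gives 10%. The median change of all genes was -0.11 in wild type and -0.13 in mutant, and changes are relative to the 75th percentile of each array. With slide as a block 6544 genes passed, 5976 of them among the 6235, and within slide 1 349 passed. Of 47 genes named here that passed, 45 passed with slide as a block. Slide 2 held 1 array per wild-type group, KCl from scan 3 and KNO3 from the low-gain scan, so salt and scan could not be told apart there. With scan as a block 2456 passed, 2244 of them shared, and within scan 1 none did, with 7150 at an unadjusted p under 0.05. The count rested on single arrays, as 2077 genes passed without wild-type KNO3 replicate 2, 2489 without wild-type KCl replicate 1, 3149 without wild-type KCl replicate 3 and 3450 without wild-type KNO3 replicate 3.

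The second comparison asked the same of the mutant. In KNO3 a protochlorophyllide reductase (Os04g0678700) rose by 11.22 ± 1.36, adjusted p = 0.00713, with 1 of 3 KCl arrays measuring it, and the type I chlorophyll a/b-binding protein Os01g0720500 by 8.38 ± 1.32, adjusted p = 0.0125. Ribulose bisphosphate carboxylase small subunits rose by 7.32 ± 1.05, adjusted p = 0.00927 (Os12g0291400) and 6.92 ± 1.23, adjusted p = 0.0169 (Os12g0291200). The 4,5-DOPA dioxygenase homologue Os01g0878900 rose here too, by 8.11 ± 1.21, adjusted p = 0.0105, as did a haem peroxidase (Os05g0135500, 9.08 ± 1.38, 1 of 3 KCl arrays) and a thioredoxin peroxidase (Os02g0192700, 6.38 ± 0.79). The chloroplast 20 kDa chaperonin homologue Os02g0781400 was at least 81.9-fold higher (adjusted p = 0.00742). Genes that fell included glutathione S-transferases, GSTU35 (Os10g0368100, -4.52 ± 1.06, adjusted p = 0.0388), GST 30 (Os10g0530900, -3.36 ± 0.84, with 2 of its 5 probes passing) and the tau class GST protein 3 (Os10g0527400, -3.28 ± 0.81), and an HSP70 homologue (Os05g0460000, -1.87 ± 0.30).

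None of the 7 genes of nitrate and nitrite reduction passed in the mutant, where the nitrate reductase Os08g0468100 changed by 0.26 ± 0.36, adjusted p = 0.685 and Os08g0468700 by 0.21 ± 0.29, adjusted p = 0.691. Adjusted over the list alone none passed either. The difference between genotypes did not pass for either locus (interaction -1.18 ± 0.51, adjusted p = 0.401, and -1.43 ± 0.42, adjusted p = 0.226). NADH-glutamate synthase 2 (Os05g0555600) fell by 3.07 ± 0.64 (adjusted p = 0.0267, and 0.0692 with slide as a block, 2 of 3 KNO3 arrays), opposite to its rise in wild type. Glucose-6-phosphate dehydrogenase (Os03g0412800) rose by 2.04 ± 0.41 and the leaf isozyme of ferredoxin-NADP reductase (Os06g0107700) by 2.43 ± 0.61. In ammonium assimilation, of 14 genes, 0 rose and 2 fell (adjusted over the list alone, 2 and 2). The nitrate transporter list shifted up (median 0.98, adjusted p = 0.00886, adjusted p = 0.289 with an estimated correlation). Of 11 genes, 0 rose and 0 fell (adjusted over the list alone, 4 and 0), and the median was 0.73 with slide as a block and 0.72 within slide 1. IAA23 (Os06g0597000, 1.27 ± 0.32) rose and HAK1 (Os03g0574900, -2.28 ± 0.50, 1 of 3 KNO3 arrays) fell.

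Photosynthetic light reactions shifted up in the mutant (median 1.57, adjusted p = 1.43e-11, adjusted p = 0.652 with an estimated correlation). Of 71 genes, 16 rose and 0 fell (adjusted over the list alone, 30 and 2), and the median was 1.82 with slide as a block and 1.97 within slide 1. The photosystem II subunit PsbS (Os01g0869800) rose by 4.17 ± 0.59, the photosystem I subunit N (Os03g0731100) by 3.93 ± 0.56 and the type II chlorophyll a/b-binding protein Os09g0439500 by 4.13 ± 0.59. The Calvin cycle and photorespiration shifted up (median 1.19, adjusted p = 3.41e-05, adjusted p = 0.289 with an estimated correlation). Of 19 genes, 3 rose and 0 fell (adjusted over the list alone, 8 and 0), and the median was 1.45 with slide as a block and 1.17 within slide 1. A glycine cleavage H protein (Os10g0516100) rose by 5.05 ± 0.80. Expansins and cellulose synthases shifted up (median 1.11, adjusted p = 9.63e-05, adjusted p = 0.462 with an estimated correlation). Of 50 genes, 3 rose and 0 fell (adjusted over the list alone, 6 and 0), and the median was 0.92 with slide as a block and 0.99 within slide 1. Sucrose, starch and trehalose metabolism shifted up (median 0.25, adjusted p = 0.0306, adjusted p = 0.389 with an estimated correlation). Of 50 genes, 3 rose and 0 fell (adjusted over the list alone, 7 and 0), and the median was 0.37 with slide as a block and 0.38 within slide 1. A glucose-1-phosphate adenylyltransferase (Os08g0345800) rose by 2.11 ± 0.47. Heat shock proteins shifted down (median -0.40, adjusted p = 0.0306, adjusted p = 0.479 with an estimated correlation, adjusted p = 0.0733 with slide as a block). Of 138 genes, 2 rose and 10 fell (adjusted over the list alone, 4 and 18), and the median was -0.41 with slide as a block and -0.32 within slide 1. The low molecular weight heat shock protein Os02g0758000 fell by 2.49 ± 0.37, with 1 of its 3 probes passing. Cytosolic ribosomal proteins shifted down (median -0.76, adjusted p = 1.65e-16, adjusted p = 0.632 with an estimated correlation). Of 140 genes, 0 rose and 1 fell (adjusted over the list alone, 0 and 0), and the median was -0.83 with slide as a block and -0.92 within slide 1. The 60S protein L26B (Os01g0140500) fell by 1.06 ± 0.27. Histone H4 (Os04g0583600, 2.85 ± 0.45) and histone H2A (Os03g0279200, 2.51 ± 0.40) rose.

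In the mutant 1470 genes passed, 1133 higher and 337 lower, a share of 77.1% higher that was 58.9% after normexp background correction, where 3106 passed, and 58.8% with probes well above background on all 12 arrays (967 and 678). It was 87.9% without a filter on dim probes, where 808 passed, and 50.4% with array weights, where 5858 passed. Replicates did not overlap for any of the 1470, and for 31% of all genes. A slide block in the fit left 495 genes, 426 of them shared, and within slide 1, with 1 mutant KNO3 array, none passed, with 3895 at an unadjusted p under 0.05 in limma. Of 29 genes named here that passed, 19 passed with slide as a block. With scan as a block none passed and 5551 had an unadjusted p under 0.05, and within scan 1 the counts were 0 and 4102. Without mutant KNO3 replicate 3 the count was 42, without mutant KCl replicate 3 it was 233, without mutant KCl replicate 2 it was 665, without mutant KNO3 replicate 1 it was 719 and without wild-type KCl replicate 3, which entered through the shared estimate of the spread, it was 934.

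The nitrate effects of wild type and mutant, which share no array, correlated across genes at r = 0.634 (rho = 0.587), and genes are not independent replicates. Of the genes that passed in each, 662 were higher and 190 lower in KNO3 in both, where independent lists would share 115.8 and 39, and 8 passed in opposite directions. RCc3 (Os04g0554800) was at least 35.3-fold higher in KNO3 in wild type and at least 18.6-fold higher in mutant, and the NB-ARC protein Os11g0654100 rose in both (4.90 ± 0.75 in mutant, 1 of 3 KCl arrays). Over the 6845 genes that passed in either genotype, 88.2% had the same sign. The correlation was 0.530 with slide as a block, 0.540 within slide 1, 0.475 with scan as a block and 0.483 within scan 1.

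**Figure D3:**
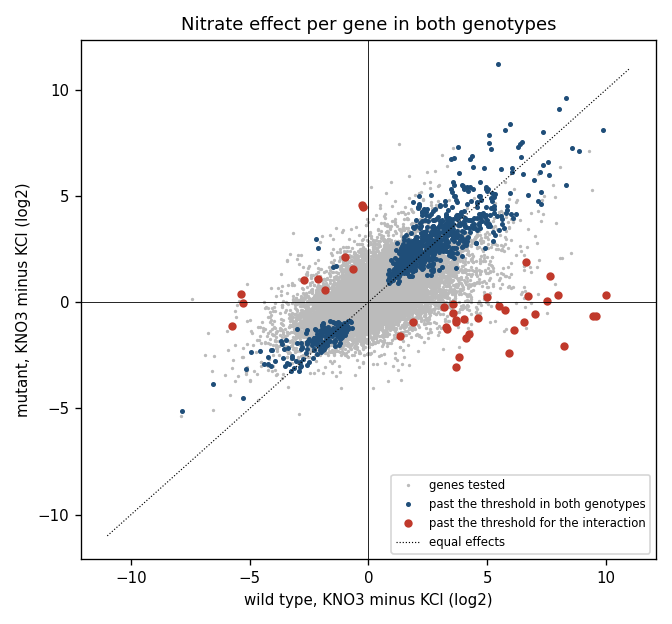
Change from KCl to KNO3 of each of the 28607 genes tested, in wild type on the horizontal axis and in mutant on the vertical axis (both log2). Genes past the threshold in both genotypes and the 41 genes past it for the interaction are marked, and the dotted line marks equal changes.

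The interaction asked for which genes the nitrate effect differed between genotypes, and 41 genes passed, 31 of them with a lower (less positive or more negative) effect in the mutant. The phosphoenolpyruvate carboxykinase Os10g0204400 rose in wild type and did not pass in mutant, a difference of -10.32 ± 1.43, adjusted p = 0.0282. The same held for the EF-hand protein Os09g0483500 (-10.12 ± 0.96, adjusted p = 0.00675), an early nodulin (Os06g0142200, -7.62 ± 0.81) and the glutathione S-transferase TSI-1 (Os10g0530000, -9.70 ± 1.37, not well above background in wild type in KCl). NADH-glutamate synthase 2 (Os05g0555600) differed by -6.74 ± 0.91, adjusted p = 0.0282 and an alcohol dehydrogenase (Os11g0210500) by -6.39 ± 0.99, adjusted p = 0.0455. The peroxidase BP 1 (Os01g0963000), which fell in wild type and did not pass in mutant, differed by 4.61 ± 0.45, adjusted p = 0.0156, with 2 of its 5 probes passing.

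The nitrate and nitrite reduction list shifted down, that is to a lower effect in mutant (median -1.43, adjusted p = 0.0228, adjusted p = 0.524 with an estimated correlation). Of 7 genes, 0 had a higher and 0 a lower effect in mutant (adjusted over the list alone, 0 and 1), and the median was -1.32 with slide as a block and -0.95 within slide 1. The ethylene list did too (median -0.13, adjusted p = 0.0231, adjusted p = 0.396 with an estimated correlation). Of 39 genes, 0 had a higher and 0 a lower effect in mutant (adjusted over the list alone, 0 and 5), and the median was -0.22 with slide as a block and -0.48 within slide 1. Their adjusted p was 0.0507 and 0.158 with slide as a block. Photosynthetic light reactions shifted up, to a higher effect in mutant (median 0.82, adjusted p = 0.000453, adjusted p = 0.927 with an estimated correlation). Of 71 genes, 0 had a higher and 0 a lower effect in mutant (adjusted over the list alone, 0 and 0), and the median was 1.39 with slide as a block and 1.17 within slide 1. With slide as a block 13 genes passed, 10 of them among the 41, and with scan as a block 1. Of 17 genes named for the interaction, 6 passed with slide as a block. Within slide 1 and within scan 1, each with 1 mutant KNO3 array, none passed, and 1780 and 2169 had an unadjusted p under 0.05 in limma. Leaving out wild-type KNO3 replicate 1 raised the count to 657. Without wild-type KNO3 replicates 2 and 3 it was 9 and 26, without wild-type KCl replicates 1, 2 and 3 it was 8, 10 and 6, without mutant KCl replicates 1 and 3 it was 6 and 10, and without mutant KNO3 replicates 1, 2 and 3 it was 18, 3 and 6.

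The genotype comparison in KCl asked how the mutant differs without nitrate. Several genes measured on all wild-type KCl arrays were not well above background on any mutant KCl array. The IN2-2 homologue Os04g0338100 was at least 1790-fold lower (adjusted p = 8.95e-08), the KIP1-like protein Os01g0168100 at least 547-fold lower and the nitrate transporter NTL1 homologue Os06g0581000 at least 492-fold lower. The RNA-binding protein Os06g0170500 was at least 414-fold lower and a 12-oxophytodienoic acid reductase (Os06g0215900) at least 93.2-fold lower (adjusted p = 6.58e-06). A protein kinase (Os11g0694100) was at least 72.3-fold higher in the mutant, the glucosyltransferase Os04g0206500 at least 30.1-fold and a calmodulin-like protein (Os12g0228800) at least 12.3-fold. Casein kinase II alpha (Os03g0762000) rose by 4.09 ± 0.28, adjusted p = 1.38e-05 and the AKT1-like potassium channel Os01g0648000 by 1.75 ± 0.35, adjusted p = 0.0453.

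Among NB-LRR disease resistance genes in KCl, of 152 genes, 0 rose and 7 fell (adjusted over the list alone, 1 and 9). Those that fell included Os11g0229500 (at least 234-fold), Os11g0686500 (at least 12.7-fold), Os01g0781100 (at least 10.7-fold) and Os11g0684100 (at least 5.49-fold). The list as a whole did not shift (adjusted p = 0.986). A thaumatin-like protein (Os12g0629700) was at least 3.1-fold lower, an Hsp70 family member (Os11g0696600) at least 30-fold lower and a glucose-1-phosphate adenylyltransferase (Os11g0204600) at least 42.6-fold lower. Os11g0229500, Os11g0686500, Os11g0696600 and Os11g0204600 lay in windows of 20 tested loci with 8 or more called for the average genotype effect. So did the NTL1 homologue Os06g0581000 and the kinase Os11g0694100. Chromosome segments that differ between the lines may account for such genes, so a response to the loss of RGA1 is left open. Cytokinin dehydrogenase 1 (Os08g0460600, -2.63 ± 0.52, adjusted p = 0.0416) and the ammonium transporter Os02g0620600 (-2.35 ± 0.47, adjusted p = 0.049, 2 of 3 mutant arrays) fell. None of the 7 genes of nitrate and nitrite reduction passed, genome-wide or adjusted over the list alone. Cytosolic ribosomal proteins shifted up (median 0.24, adjusted p = 0.000615, adjusted p = 0.983 with an estimated correlation). Of 140 genes, 0 rose and 0 fell (adjusted over the list alone, 0 and 0), and the median was 0.26 with slide as a block and 0.32 within slide 1. Photosynthetic light reactions did not pass (median -0.43, adjusted p = 0.159) but shifted down with slide as a block (median -0.71, adjusted p = 0.000131, and 0.944 with an estimated correlation).

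In all, 266 genes passed in KCl, 85 higher and 181 lower in the mutant. The balance was 179 and 185 without mutant KCl replicate 2, and 41 and 27 with probes well above background on all 12 arrays. Replicates did not overlap for any of the 266 and for 20.3% of all genes. With slide as a block 274 passed, 235 of them shared, within slide 1 141, with scan as a block 282, 171 of them shared, and within scan 1 91. Of 21 named genes that passed, 18 passed with slide as a block. Slide 2 held no mutant KCl array.

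In KNO3 the same comparison gave the genotype difference under nitrate. The IN2-2 homologue (Os04g0338100, at least 43.5-fold), the KIP1-like protein (Os01g0168100, at least 848-fold) and the NTL1 homologue (Os06g0581000, at least 298-fold) were lower in the mutant here too. The kinase Os11g0694100 (at least 36.6-fold), the glucosyltransferase Os04g0206500 (at least 16.1-fold) and casein kinase II alpha (Os03g0762000, 4.27 ± 0.28, adjusted p = 9.58e-06, with 2 of its 3 probes passing) were higher. The EF-hand proteins Os09g0483500 (-7.58 ± 0.68, adjusted p = 0.000119) and Os09g0483100 (at least 125-fold) fell, as did the glutathione S-transferase TSI-1 (Os10g0530000, -6.02 ± 0.97). The chitinases Os08g0518900 (-4.25 ± 0.54) and Os11g0701000 (class III, -5.93 ± 1.16) fell, while the peroxidase BP 1 (Os01g0963000) rose by 4.22 ± 0.35, adjusted p = 0.000287, with 2 of its 5 probes passing.

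In nitrogen metabolism under nitrate, NADH-glutamate synthase 2 (Os05g0555600) fell by 4.20 ± 0.64 (adjusted p = 0.00569, 2 of 3 mutant arrays). Another NADH-glutamate synthase (Os04g0490000) fell by 3.57 ± 0.80 (adjusted p = 0.0426, 2 of 3 mutant arrays). The locus Os08g0468700 fell by 1.36 ± 0.29 (adjusted p = 0.0374) and the nitrate reductase Os08g0468100 did not pass (-1.08 ± 0.36, adjusted p = 0.149). The nitrate and nitrite reduction list shifted down (median -1.09, adjusted p = 0.0322, adjusted p = 0.404 with an estimated correlation, adjusted p = 0.0701 with slide as a block and 0.108 with the list as first written). Of 7 genes, 0 rose and 1 fell (adjusted over the list alone, 0 and 3), and the median was -1.01 with slide as a block and -0.65 within slide 1. The haemoglobins Os03g0234000 (-3.22 ± 0.64) and Os03g0234100 (at least 3.86-fold, 2 of 3 wild-type arrays) fell. The ethylene list shifted down (median -0.30, adjusted p = 0.0322, adjusted p = 0.375 with an estimated correlation, adjusted p = 0.0701 with slide as a block). Of 39 genes, 0 rose and 4 fell (adjusted over the list alone, 0 and 6), and the median was -0.33 with slide as a block and -0.30 within slide 1. An ethylene receptor (Os04g0169100, -2.31 ± 0.28) and the ethylene responsive element binding protein 2 (Os05g0361700, -3.08 ± 0.53) fell. Photosynthetic light reactions shifted up (median 0.41, adjusted p = 0.0322, adjusted p = 0.95 with an estimated correlation). Of 71 genes, 1 rose and 0 fell (adjusted over the list alone, 1 and 0), and the median was 0.71 with slide as a block and 0.61 within slide 1. The 22 kDa protein of photosystem II (Os04g0690800) rose by 2.52 ± 0.48. The histone H1 variant Os07g0184800 (-2.86 ± 0.49) and the histone H4 genes Os09g0553100 (-1.75 ± 0.31) and Os03g0119900 (-1.93 ± 0.38) fell. Among cell cycle and histone genes, of 96 genes, 0 rose and 6 fell (adjusted over the list alone, 0 and 7), without a shift of the list (adjusted p = 0.126). Sucrose synthase 2 (Os06g0194900) fell by 2.08 ± 0.33. Among NB-LRR genes, of 152 genes, 1 rose and 8 fell (adjusted over the list alone, 4 and 11).

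In KNO3 729 genes passed, 217 higher and 512 lower in the mutant. Replicates did not overlap for any of the 729 and for 19.6% of all genes. A slide block in the fit left 662 genes, 576 of them shared, within slide 1, with 1 mutant KNO3 array, 88 and within slide 2, the same arrays as scan 4, 116. With scan as a block 528 passed, 425 of them shared, and within scan 1 52. Of 26 named genes that passed, 23 passed with slide as a block. Without wild-type KNO3 replicate 1 the count was 2754, 1269 higher and 1485 lower. It was 339 without wild-type KNO3 replicate 2, 426 without wild-type KNO3 replicate 3, and 476, 424 and 369 without mutant KNO3 replicates 1, 2 and 3.

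The genotype effects in the 2 salts, which share no array, correlated across genes at r = 0.299 (rho = 0.127). Of the genes that passed in each, 41 were higher and 124 lower in the mutant in both salts, where independent lists would share 0.645 and 3.24, and 1 passed in opposite directions. The correlation was 0.181 with slide as a block, 0.313 within slide 1, 0.265 with scan as a block and 0.283 within scan 1.

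Averaged over genotypes, 8969 genes passed for nitrate, 4020 higher and 4949 lower. The balance turned with normexp background correction (4423 higher and 4324 lower), within slide 1 (793 and 561), with scan as a block (1362 and 961) and without the 3 low-gain arrays (2082 and 1926). Among the genes that passed were the DOPA dioxygenase homologue Os01g0878900 (8.99 ± 0.85, adjusted p = 0.000487) and GST6 (Os09g0367700, -6.62 ± 1.11, adjusted p = 0.00273). Nitrate transporters shifted up (median 0.52, adjusted p = 0.0176, adjusted p = 0.291 with an estimated correlation). Of 11 genes, 5 rose and 0 fell (adjusted over the list alone, 5 and 0), and the median was 0.50 with slide as a block and 0.74 within slide 1. The auxin list shifted up (median 0.21, adjusted p = 0.0342, adjusted p = 0.167 with an estimated correlation, adjusted p = 0.057 with slide as a block). Of 106 genes, 23 rose and 10 fell (adjusted over the list alone, 23 and 10), and the median was 0.22 with slide as a block and 0.23 within slide 1. Photosynthetic light reactions (median 1.01, adjusted p = 1.79e-06, adjusted p = 0.687 with an estimated correlation), the Calvin cycle and photorespiration (median 0.97, adjusted p = 0.000237, adjusted p = 0.291 with an estimated correlation) and expansins and cellulose synthases (median 1.08, adjusted p = 0.000237, adjusted p = 0.537 with an estimated correlation) shifted up. Their medians were 1.29, 1.14 and 1.21 with slide as a block and 1.75, 1.07 and 0.93 within slide 1. Ammonium transporters (median -1.01, adjusted p = 0.0176, adjusted p = 0.537 with an estimated correlation) and cytosolic ribosomal proteins (median -0.68, adjusted p = 1.8e-12, adjusted p = 0.671 with an estimated correlation) shifted down. Their medians were -0.96 and -0.70 with slide as a block and -0.60 and -0.69 within slide 1. With slide as a block 7564 genes passed, 6941 of them shared, and within slide 1 1354. With scan as a block 2323 passed, 2076 of them shared, and within scan 1 none, with 8022 at an unadjusted p under 0.05 in limma.

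Averaged over salts, 692 genes passed for genotype, 201 higher and 491 lower in the mutant, among them casein kinase II alpha (Os03g0762000, 4.18 ± 0.20, adjusted p = 3.47e-07) and RGA1 (Os05g0333200, -5.49 ± 0.24, adjusted p = 1.38e-07). No list shifted for the average genotype effect, and the lowest adjusted p was that of the cytosolic ribosomal proteins (0.129). A slide block in the fit left 673 genes, 625 of them shared, within slide 1 201, with scan as a block 646, 437 of them shared, and within scan 1 138. With array weights, chosen after the data were seen, 12408 genes passed in wild type, 2112 in KCl (1004 higher and 1108 lower), 3616 in KNO3 (1704 and 1912), 1335 for the interaction (663 and 672), 14028 for the average nitrate effect and 4093 for the average genotype effect. Leaving out wild-type KNO3 replicate 1 gave 2169 (937 higher and 1232 lower), mutant KCl replicate 3 429, wild-type KNO3 replicate 2 438, wild-type KCl replicate 2 455 and wild-type KCl replicate 1 456.

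**Figure D4:**
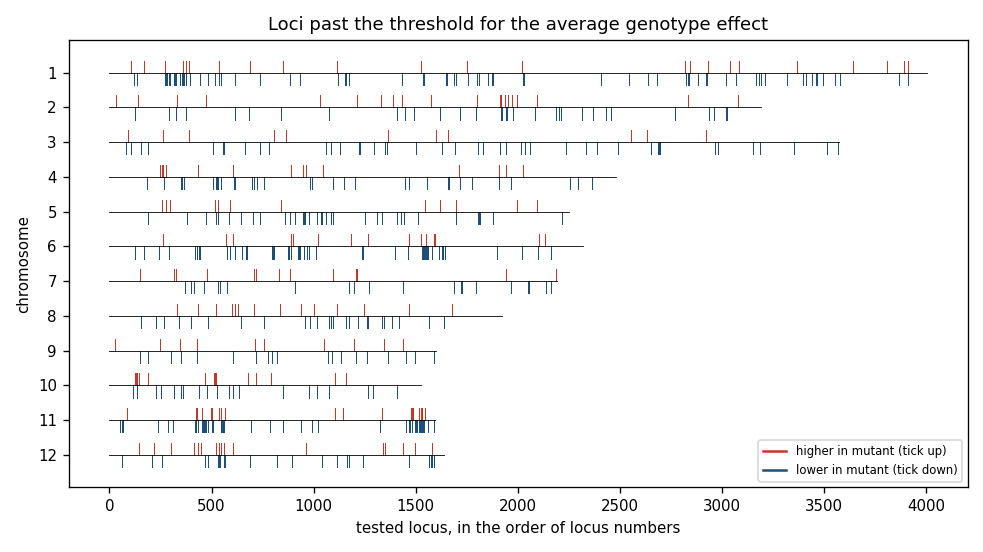
Tested loci past the threshold for the average genotype effect, in the order of their locus numbers on each of 12 chromosomes. Ticks point up for loci higher in the mutant and down for loci lower in it, and chromosome 11 has the highest share, 81 of 1595 tested loci.

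Other lists did not shift in either nitrate comparison. The genes that rose and fell in wild type, with the numbers adjusted over the list alone in brackets, were as follows. The results were ammonium assimilation 1 and 0 of 14 (1 and 0), reductant and carbon supply 2 and 2 of 17 (4 and 3), nitrate response regulators 5 and 1 of 13 (5 and 2), and heterotrimeric G protein subunits 2 and 0 of 7 (2 and 1). In hormone lists they were gibberellin 1 and 1 of 16 (0 and 1), brassinosteroid 2 and 0 of 22 (2 and 0), cytokinin 4 and 2 of 25 (6 and 4), abscisic acid and dehydration 3 and 3 of 40 (3 and 3), ethylene 9 and 3 of 39 (9 and 4) and jasmonate 2 and 1 of 25 (2 and 1). Further results in wild type were pathogenesis-related proteins 12 and 10 of 90 (13 and 10), NB-LRR disease resistance proteins 17 and 19 of 152 (17 and 19) and WRKY transcription factors 6 and 4 of 70 (3 and 4). Those of the remaining lists were cell cycle and histones 16 and 4 of 96 (16 and 4), root markers 1 and 1 of 8 (1 and 1), seed and pollen markers 1 and 2 of 17 (2 and 2), peroxidases and glutathione transferases 24 and 22 of 156 (25 and 23), potassium and phosphate transport 7 and 13 of 44 (7 and 13) and circadian clock 1 and 0 of 6 (1 and 0). In wild type heat shock proteins had 7 and 19 of 138 (7 and 19) and sucrose, starch and trehalose metabolism 9 and 6 of 50 (9 and 6), and neither list shifted. In mutant the ammonium transporters had 0 and 0 of 10 (0 and 0), the auxin list 2 and 1 of 106 (0 and 1), reductant and carbon supply 2 and 0 of 17 (3 and 2), jasmonate 1 and 0 of 25 (1 and 0), pathogenesis-related proteins 3 and 3 of 90 (3 and 3), NB-LRR proteins 4 and 1 of 152 (4 and 0) and WRKY transcription factors 0 and 2 of 70 (0 and 0). Cell cycle and histones had 6 and 0 of 96 (8 and 0) in mutant, root markers 1 and 0 of 8 (1 and 0), seed and pollen markers 0 and 0 of 17 (3 and 1), peroxidases and glutathione transferases 13 and 4 of 156 (16 and 11) and potassium and phosphate transport 1 and 2 of 44 (2 and 7). In mutant 0 genes passed, genome-wide or adjusted over the list alone, among nitrate response regulators, heterotrimeric G protein subunits, gibberellin, brassinosteroid, cytokinin, abscisic acid and dehydration, ethylene and circadian clock. The direction of the list test and the sign of the list median differed for 5 lists in wild type, 5 in mutant, 6 in KCl and 7 in KNO3, none of which passed. The diterpenoid phytoalexin list had 3 tested genes and no list test. Of these the ent-kaurene synthase like-2 (Os04g0611700) rose with nitrate in mutant (1.76 ± 0.40, adjusted p = 0.0354). It was at least 1.03-fold higher with nitrate in wild type, where 1 of 3 KNO3 arrays measured it. It was higher in the mutant than in wild type in KCl (at least 4.75-fold) and in KNO3 (3.96 ± 0.40, 1 of 3 wild-type arrays). The kaurene synthase A homologue (Os02g0278700) rose with nitrate in wild type (1.36 ± 0.44, adjusted p = 0.0485) and did not pass in mutant (1.55 ± 0.44, adjusted p = 0.0651) or between genotypes, and the ent-kaurene synthase 1A homologue (Os12g0491800) passed in no comparison (-0.64 ± 1.02 with nitrate in wild type, with 1 of 3 arrays of each salt measuring it).

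**Figure D5:**
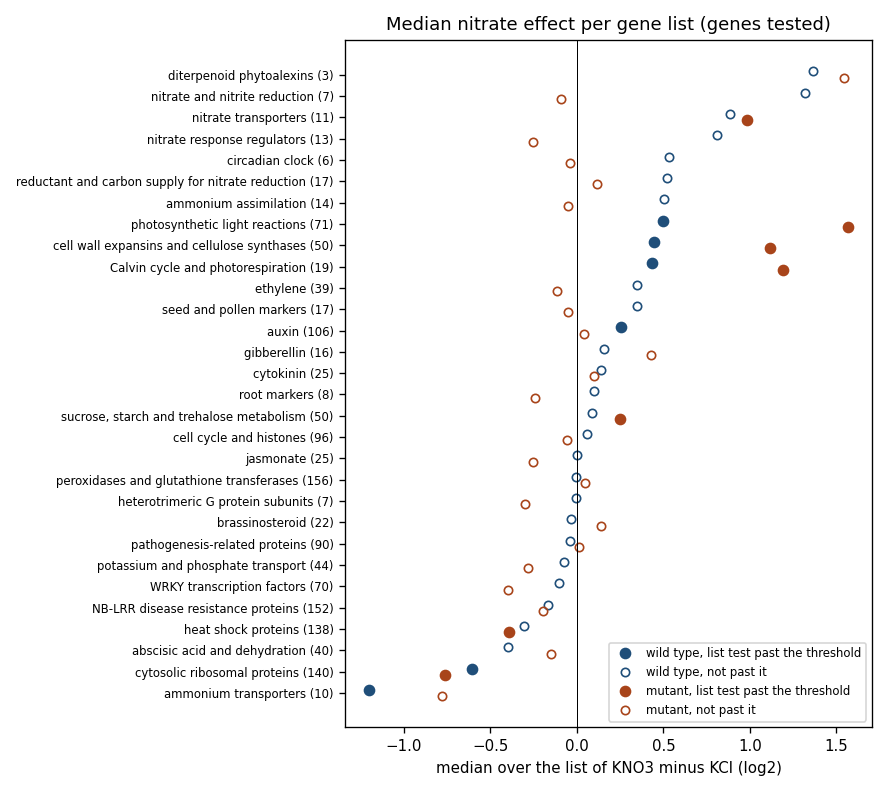
Median change from KCl to KNO3 (log2) over the tested genes of each list, in wild type and mutant, with filled points where the list test passed with the preset correlation. The number of genes is in brackets, and medians run from -1.20 for ammonium transporters in wild type to 1.57 for photosynthetic light reactions in mutant.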

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

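The tests of chromosome segments and of single-probe mismatches, and the count of neighbouring pairs without names, were chosen after the results they measure had been seen, and the other tests before. The jackknife errors beside the size of the nitrate effect, the array weights and residuals, the effect sizes beside the low-gain scan, and the standard error and the restriction to pairs with names in the test of gene copies, were added after those values were seen. No test of single outlying arrays was made within the groups of 3. The residuals from the group means were largest on wild-type KNO3 replicate 1, with a root mean square of 0.801 against 0.446 to 0.692 on the other 11 arrays, and its limma array weight was 0.366, the lowest. Without it 2754 genes passed in KNO3 (729 with it) and 657 for the interaction (41 with it).

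A test of the difference itself, the interaction of salt and genotype, drew attention to 41 genes whose nitrate effect differed between wild type and mutant. Of these, 38 passed for nitrate in wild type and 7 in mutant, and 32 had opposite signs in the genotypes. As only 7 passed in mutant, most of the opposite signs rest on mutant effects that did not pass, and a choice by the interaction favours such signs. The nitrate effect was lower in mutant than in wild type for the phosphoenolpyruvate carboxykinase Os10g0204400 (-10.32 ± 1.43), the EF-hand proteins Os09g0483100 (-10.21 ± 1.29) and Os09g0483500 (-10.12 ± 0.96), the glutathione S-transferase TSI-1 (Os10g0530000, -9.70 ± 1.37), the early nodulin Os06g0142200 (-7.62 ± 0.81) and the kelch protein Os08g0128000 (-7.50 ± 0.93). It was also lower for the ADR11 homologue Os06g0643500 (-7.48 ± 1.16), NADH-glutamate synthase 2 (Os05g0555600, -6.74 ± 0.91), the 2OG-Fe(II) oxygenase Os03g0439500 (-6.40 ± 0.72), an alcohol dehydrogenase (Os11g0210500, -6.39 ± 0.99), the alpha/beta hydrolase Os11g0138900 (-6.12 ± 0.97) and, chosen after its values were seen, the pyruvate decarboxylase Os03g0293500 (-3.40 ± 0.53). It was higher in mutant for the cytochromes P450 Os10g0166600 (5.75 ± 0.90) and Os02g0570500 (3.79 ± 0.60), the peroxidase BP 1 (Os01g0963000, 4.61 ± 0.45), the nuclear hormone receptor domain protein Os02g0597800 (2.40 ± 0.38) and the transcription termination factor Os02g0749800 (2.22 ± 0.34). The IN2-2 homologue Os04g0338100 had 5.21 ± 0.66 in the fit, with no mutant array well above background. Each value is a difference of log2 changes with its standard error. The probes that passed were 1 of 6 for Os03g0439500, 1 of 3 for Os02g0749800, 2 of 5 for Os01g0963000, 2 of 3 for Os11g0210500 and 1 of 2 for Os08g0128000 and for Os11g0138900, and the other probes of these genes went in the same direction. Os09g0483100, Os10g0530000, Os06g0643500, Os03g0439500 and Os11g0138900 were not well above background on any array of wild type in KCl, nor Os10g0166600 and Os02g0570500 in wild type in KNO3, nor Os08g0128000 in mutant in KNO3. Nor were Os09g0483100, Os03g0439500 and Os02g0570500 in mutant in KCl, or Os09g0483100 in mutant in KNO3. Their values rest on signals near background, and such fitted values are no bounds. Os06g0142200, Os11g0210500 and Os03g0293500 were called lower in the mutant for the average genotype effect, beside a neighbouring tested locus called lower too. Os09g0483100 and Os09g0483500 were called lower there as well, close to Os09g0483300, also called lower. Chromosome segments that differ between the lines stay open for these genes and were not tested for the interaction. Among 100 splits of genotype within salt, 3 gave as many genes as the real 41, and the highest of the others gave 58. Such splits also break up the genotype effect itself, so they cannot tell whether chance would give 41 genes for the interaction. The count was 13 with slide as a block and 1 with scan as a block, and it ran from 3 without mutant KNO3 replicate 2 to 657 without wild-type KNO3 replicate 1.

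Other splits of the arrays were counted for each comparison. For 3 arrays against 3 the 10 splits are too few for a share under 0.05. The real split gave 6235 genes in wild type and 1470 in mutant, where the highest other split gave 1 in each, 266 in KCl (highest other 0), and 729 in KNO3 (highest other 287). In each of these comparisons 1 split, the real one, gave as many genes. For the average nitrate effect 1 of 100 splits, the real one, gave 8969 genes (highest other 2339), and for the average genotype effect 1 of 100 gave 692 (highest other 58), a share under 0.05 for both counts. The correlation of the nitrate effects (0.634, highest other 0.583) and that of the genotype effects (0.299, highest other 0.226) were each reached by 1 of 100 splits, a share under 0.05 for both. The splits treat the arrays as exchangeable, although the low-gain scan held nitrate arrays only, so these shares do not exclude chance. As many as the 7 lists called for the average nitrate effect were called in 6 of 100 splits (highest other 9), and chance is not excluded. With 0 lists called for the average genotype effect, 100 of 100 splits called as many by construction (highest other 7), so that count decides nothing.

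Genes that differed between mutant and wild type lay side by side. In the order of locus numbers, which stood in for coordinates, 71 pairs of neighbouring tested loci were called in the same direction for the average genotype effect, against a median of 10 and a highest of 21 in 1000 random sets, and against 21 among 683 nitrate genes. Single-probe mismatches as the whole cause were argued against for called genes with other tested probes. There 83.5% of 339 other probes moved the same way by at least 50% of the size. The 692 called genes had only these 339 other probes, so mismatches stay open for genes with 1 tested probe. Of the 15 pairs with names on both sides, 6.67% (standard error 6.44) had the same description. Whole descriptions were compared, so copies of 1 gene described in different words counted as different. The test therefore cannot decide on copies that share a probe target. Such copies stay open for these 15 pairs and for the other 56 pairs, whose names could not be compared. Chromosome segments that differ between the lines may account for the neighbouring pairs (71), which would leave open whether any single gene among them responds to the loss of RGA1, and the labels do not state how the lines are related.

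Of the 6 nitrate arrays, 3 came from the scan with the low gain. Low gain as the whole cause of the nitrate effect was argued against, since the effect in scan 1 nitrate arrays and that in low-gain nitrate arrays, computed with no shared array, correlated across genes at 0.686 to 0.707 in wild type and 0.368 to 0.651 in mutant, over the 3 choices of the KCl array. In mutant 0 genes passed with scan as a block (5551 at an unadjusted p under 0.05 in limma). There the median standard error over the 1470 genes called rose from 0.472 to 0.610, and the residual degrees of freedom fell from 8 to 5. The median effect over these 1470 genes was 2.31 as reported and 2.31 with scan as a block. It was 2.25 without the 3 low-gain arrays, which leaves 1 mutant KNO3 array. Over the 8969 genes called for the average nitrate effect the median in mutant was 1.01 as reported, 0.871 with scan as a block and 0.916 without the 3 low-gain arrays. Both sets of genes were chosen with the low-gain arrays included, so their medians cannot tell whether the scan had a share. The design varied the salt, KNO3 against KCl, so nitrate and chloride changed together and their parts cannot be told apart. A part played by the scan in single genes was not tested.

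The nitrate effect was smaller in the mutant for 6062 of the 8969 genes called for the average nitrate effect (67.6%), with a median effect of 1.37 in wild type and 1.01 in mutant, signed by the average. The median difference was -0.345 with a jackknife error of 0.303. These genes were chosen by the average and not by their wild-type result. With a difference so close to its error, the test cannot tell a smaller effect from none, and does not decide on a choice of genes by their wild-type result. The difference lay between -0.513 and -0.221 whichever array was left out. The smallest, without mutant KNO3 replicate 2, was below the jackknife error in size, so a single array as the cause stays open. The low-gain scan stays open, since the difference was -0.353 within scan 1 and -0.391 with scan as a block, where the jackknife error was 0.314. Chance is not excluded, as 21 of 100 splits of genotype within salt gave a difference as large (0.345, highest other 0.656), and a smaller effect in the mutant is a hypothesis.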

How the results depend on the processing

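Scan as a block, scan 1 alone, scan 4 alone, leaving out the 3 arrays of the low-gain scan, array weights, and the lists as first written were chosen after the data were seen. Other settings were chosen before. Where no reason is given, the cause was not tested.

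With normexp background correction 3106 genes passed for nitrate in mutant and 70 for the interaction, and the correlation of the genotype effects was 0.2195. Quantile normalization and the value table left each count within 1.5 times the reported one. Without a filter on dim probes 808 genes passed for nitrate in mutant and 22 for the interaction, and the correlations were 0.574 for nitrate and 0.259 for genotype. With probes well above background on all 12 arrays, where fewer genes were tested (20697), 68 passed in KCl, 476 in KNO3 and 451 for the average genotype effect, the correlation of the genotype effects was 0.1745, and 77 of the 148 named results that passed were kept, largely since dim genes were not tested. With a test per probe, and so more tests, 10231 probes passed in wild type, 3180 in mutant, 1123 in KNO3, 70 for the interaction and 14588 for the average nitrate effect, 59 list tests passed, and the correlation of the genotype effects was 0.2805.

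With slide as a block 495 genes passed in mutant and 13 for the interaction, and the correlations were 0.5302 for nitrate and 0.1813 for genotype. With slide 1 alone, with fewer samples, 349 genes passed in wild type, 0 in mutant, 141 in KCl, 88 in KNO3, 0 for the interaction, 1354 for the average nitrate effect and 201 for the average genotype effect. The unadjusted counts beside the zeros, in limma, were 3895 and 1780. The correlation of the nitrate effects was 0.5402 and 37 named results were kept. With slide 2 alone each wild-type group had 1 array, and lone samples were assumed to vary like the mutant KNO3 arrays. In wild type the salts there came from different scans, so salt and scan could not be told apart.

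Scans 2 and 3 hold 1 array each, so scan as a block removes those arrays. It gave 2456 genes in wild type, 0 in mutant (5551 unadjusted, in limma), 1 for the interaction and 2323 for the average nitrate effect, correlations of 0.4751 for nitrate and 0.2654 for genotype, and 80 named results. Scan 1 alone, with fewer samples, gave 0 genes in wild type, 0 in mutant, 91 in KCl, 52 in KNO3, 0 for the interaction, 0 for the average nitrate effect and 138 for the average genotype effect, with 7150, 4102, 2169 and 8022 unadjusted beside the zeros in limma. The nitrate correlation there was 0.4829 and 18 named results were kept. Scan 4 alone gave 116 genes in KNO3. Without the 3 arrays of the low-gain scan 3090 genes passed in wild type, 10 in mutant, 123 in KNO3, 0 for the interaction (2044 unadjusted, in limma), 4008 for the average nitrate effect and 248 for the average genotype effect, the nitrate correlation was 0.5583 and 68 named results were kept.

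With limma array weights, estimated from the same residuals as the spread and stopped before they converged, 12408 genes passed in wild type, 5858 in mutant, 2112 in KCl, 3616 in KNO3, 1335 for the interaction, 14028 for the average nitrate effect and 4093 for the average genotype effect. The correlations were 0.5914 for nitrate and 0.2454 for genotype, and the share of higher genes was 50.4% in mutant, 47.5% in KCl and 47.1% in KNO3.

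The replicate numbers did not pair the arrays. Of 18 pairs across groups 3 correlated over 0.1, from -0.226 to 0.394, and 3 of 12 arrays correlated best with their own number. With replicate number as a block 977 genes passed in mutant and 8 for the interaction. With the lists as first written 25 of the 27 list tests passed, among them the 5 of marker lists, while those of the Calvin cycle and photorespiration in wild type (adjusted p = 0.055, 0.0256 as reported) and of nitrate and nitrite reduction in KNO3 (0.108, 0.0322 as reported) did not. With an estimated correlation 0 of the 27 list tests passed, and 0 of the 5 tests of cell type marker lists, all 5 of photosynthetic light reactions. With a test per probe, where RGA1 counts with 7 probes, the list of heterotrimeric G protein subunits, genotype effect in KCl, changed direction and passed (adjusted p = 8.41e-05), as did that of heterotrimeric G protein subunits, average genotype effect (adjusted p = 1.35e-05). Cytosolic ribosomal proteins changed direction in KNO3 with normexp (adjusted p = 0.0399).

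Leaving out 1 array at a time gave 2077 to 8126 genes in wild type, 42 to 2085 in mutant, 186 to 364 in KCl, 339 to 2754 in KNO3, 3 to 657 for the interaction, 6173 to 10501 for the average nitrate effect and 429 to 2169 for the average genotype effect. It gave correlations of 0.57 to 0.6678 for nitrate and 0.2592 to 0.3112 for genotype, 23 to 28 list tests, 4 to 6 marker list tests and 92 to 146 named results. Between 59.9% and 69.3% of probes were well above background on an array, which limits what can be said of dim genes.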

Other observations

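The counts by kind of probe, the windows of loci and the genes of the last paragraph were chosen after the data were seen.

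The array also holds probes for antisense transcripts, microRNA precursors and organelle genes. Of 111 antisense targets tested, 17 passed for nitrate in wild type, 10 in mutant, and 0 for genotype in either salt, while 39 passed for the average nitrate effect and 6 for the average genotype effect. Of 94 microRNA precursor targets tested, 10 passed for nitrate in wild type, 6 in mutant, 0 for genotype in either salt, 23 for the average nitrate effect and 0 for the average genotype effect. Of 119 organelle targets tested, 15 passed for nitrate in wild type, 9 in mutant, 1 for genotype in KCl, 0 in KNO3, 41 for the average nitrate effect and 3 for the average genotype effect.

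Of the 692 genes called for the average genotype effect, 129 were lower in the mutant and not well above background on any mutant array, 74 of them while well above background on all 6 wild-type arrays. In the other direction, 33 were higher in the mutant and not well above background on any wild-type array. Chromosome 11 had 81 of 1595 tested loci called (5.08%), chromosome 6 had 79 of 2320 (3.41%) and chromosome 1 had 116 of 4003 (2.9%). The fullest window of 20 tested loci, Os06g0579201 to Os06g0586300, held 15 called loci, 14 of them lower in the mutant, where random sets held at most 7. Os11g0691700 to Os11g0697100 held 12, and 4 windows held 8, counting only windows whose starts lay at least 20 tested loci apart.

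The following 3 genes were picked after their values were seen, and no set of related genes was tested. A pyruvate decarboxylase (Os05g0469600) changed by 5.34 ± 0.75, adjusted p = 0.00319 in wild type and by -0.90 ± 0.75, adjusted p = 0.473 in mutant, and another (Os03g0293500) by 3.17 ± 0.38, adjusted p = 0.002 and by -0.23 ± 0.38, adjusted p = 0.731. The alcohol dehydrogenase Os11g0210500 changed by 3.81 ± 0.70, adjusted p = 0.00678 in wild type and by -2.59 ± 0.70, adjusted p = 0.0581 in mutant. The difference between genotypes was -6.24 ± 1.07, adjusted p = 0.0697 for Os05g0469600 and -3.40 ± 0.53, adjusted p = 0.0455 for Os03g0293500. All 3 genes were called lower in the mutant for the average genotype effect, each beside a neighbouring tested locus called lower too. Chromosome segments that differ between the lines therefore stay open for them. No explanation of these values was tested.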
